A study of Mus musculus with 2 samples.

How the data were processed

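Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 2 libraries from mouse embryoid bodies. Embryonic stem cells of the A2lox FMsgn1 line, which carry a doxycycline-inducible, FLAG-tagged Msgn1, were differentiated for 2 days, given doxycycline at 1 ug/ml and collected 36 h later, per the labels' protocols. One library holds DNA recovered with an antibody against the FLAG tag and the other holds input DNA, with no antibody. There was 1 library per group, so no value below has a replicate error, and no test compares replicates.

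The deposited data used here were 1 list of 4087 peaks, with a chromosome, start, end, name and score for each. Peaks were called with MACS by the authors, as the peak names in the deposited file show, for the FLAG library against input. The MACS version and settings, the aligner and the read filters are not given in the sources used here. The submitters' processing notes name CASAVA 1.4, FastQC and the mouse build mm9. The score is the authors' own value per peak, deposited with 2 decimals and without a header. No score lies below 50. MACS commonly writes 10 times the negative log10 of a p-value in this column, and on that scale a score of 50 would be a p-value of 1e-05, but nothing in the deposited file states the scale. The score is therefore used to rank and filter peaks within this list and to describe medians and their differences, whose scale is unknown. An assumed halving of scores is used for X alone. No fold enrichment, read count, summit or library total was used here, so the depth behind each peak is unknown and no interval on a peak's height can be given.

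The start positions were read as 0-based, as in BED files, and are printed 1-based. The positions were set against the only gene table at hand, which is of GRCm38.p6. On chromosomes 1, 5, 7 and 8, 42 peaks end past the last gene of that table on their chromosome. Peaks can lie past the last gene within 1 build too, so this does not settle the build. It was taken as mm9 from the submitters' processing notes. Positions were not converted. No genome sequence or gene annotation of mm9 was used here. Distances of peaks to transcription start sites, the comparison of gene lists fixed before the data were examined, the E-box and other motif counts, the motif share by rank and the count of genes with several peaks were all planned and were not run for this reason. Peaks are named by position and by the name in the deposited list, and no gene is assigned to any of them. From the GRCm38.p6 table only the number of protein-coding genes per chromosome was taken.

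The rule for single peaks, fixed before the data were examined, was to give the 20 peaks with the highest score of the authors. The parts of that rule that name genes could not be applied. The comparisons across chromosomes, of distances between peaks and of score with width were chosen after the peak list had been seen.

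Peak density was the number of peaks divided by the span from the first peak start to the last peak end of each chromosome, with 95% exact Poisson intervals, which cover counting error only. A run was defined as consecutive peaks separated by at most 50 kb, from the end of one to the start of the next, and runs of 3 or more peaks were counted. The count was compared with 1000 random placements in which each peak, at its own width, was put anywhere within the span of its chromosome, or within its own stretch of 10 Mb or 2 Mb. Placed peaks were allowed to overlap, and assembly gaps were not excluded. Medians of a subset of peaks were placed among the medians of 10000 random subsets of the same size. These placements and subsets describe this one list, since peaks are not replicates. Correlations across the 19 autosomes were tested by permutation with 100000 resamples, two-sided, and adjusted by Benjamini-Hochberg over the 2 relations computed. Alternatives were stricter score limits, joining of peaks less than 1 kb or 10 kb apart, other gap limits and other denominators.

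The run count and the X ratio were tested on simulated data of 4087 peaks. In 20 of 20 lists of randomly placed peaks, the run count lay within the range of its placements. These lists were made by the same random placement as the comparison. They check the calculation, and not whether random placement is a fair comparison for real peaks. In 20 of 20 lists with 200 planted runs, the run count lay above the highest. That is more runs than the 116 observed, so recovery of an excess of the observed size was not tested. A true X ratio of 0.25 was recovered as 0.257 on average over 20 draws. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.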

Results

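Msgn1 (mesogenin 1) is a basic helix-loop-helix transcription factor of the presomitic mesoderm, the tissue from which somites form. The series asked where it binds in the genome of differentiating embryonic stem cells. FLAG-tagged Msgn1 was switched on with doxycycline in embryoid bodies, the aggregates in which such cells differentiate, after 2 days of culture, and chromatin was collected 36 h later. The data comprised 1 FLAG ChIP library and 1 input library, without replicates, summarised by the authors as 1 list of peaks of FLAG over input. Positions are those of the authors' list, on mm9 per the submitters' processing notes. The sequencing depth is unknown from the list. Genes at the peaks were not analysed here.

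Peaks of FLAG over input were called at 4087 places, on all 19 autosomes and on X, and no listed peak was on Y, mitochondrial or unplaced sequence. The peaks covered 2.88 Mb in total and none overlapped another. Their median width was 678 bp (quartiles 574.5 and 817 bp) and the range was 296 to 3503 bp. The authors' score per peak ran from 50 to 1107 with a median of 72.8 and an upper quartile of 108, and 1228 peaks (30.05%) scored under 60. A score of at least 100 was reached by 1168 peaks (28.6%), at least 200 by 303 (7.41%) and at least 400 by 56 (1.37%).

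The 10 highest peaks stood apart from the rest of the list, with scores from 801 to 1107, while the eleventh scored 637. They lay on 9 chromosomes. The highest, at chr3:130820546-130822307, was 1762 bp wide and scored 1107. It was followed by chr18:67595531-67596941 with a score of 934, chr2:26341867-26342806 with 908, chr14:29188857-29190226 with 900.4 and chr13:57463295-57464567 with 867. Next came chr9:67083674-67084651 with a score of 854, chr11:22663000-22663975 with 841, and chr17:15577098-15578149 with 837. The last of the 10 were chr1:7010407-7011462 with a score of 831 and chr17:75864265-75865213 with 801.

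The following 10 peaks scored between 519 and 637. They were chr7:103315129-103316228, chr1:77459442-77460376, chr1:196453830-196454625, chr15:57627708-57628585, chr12:12803511-12804485, chr2:84971004-84973477, chr9:18502201-18502845, chr3:65766398-65767261, chr11:65116764-65117914 and chr3:147291713-147292597, in descending order of score. Of the 20, 10 had another peak within 50 kb, while 2860 of all 4087 peaks had none. Whether the 20 differ in this from the list was not tested. Among the 20, the closest neighbour was that of chr1:77459442-77460376, 0.43 kb away. The nearest neighbour of the fourth-ranked peak was 1.11 kb away and that of the third was 1.31 kb away, whereas that of chr9:18502201-18502845 was about 2400 kb away. No error can be given for any single score.

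**Figure D1:**
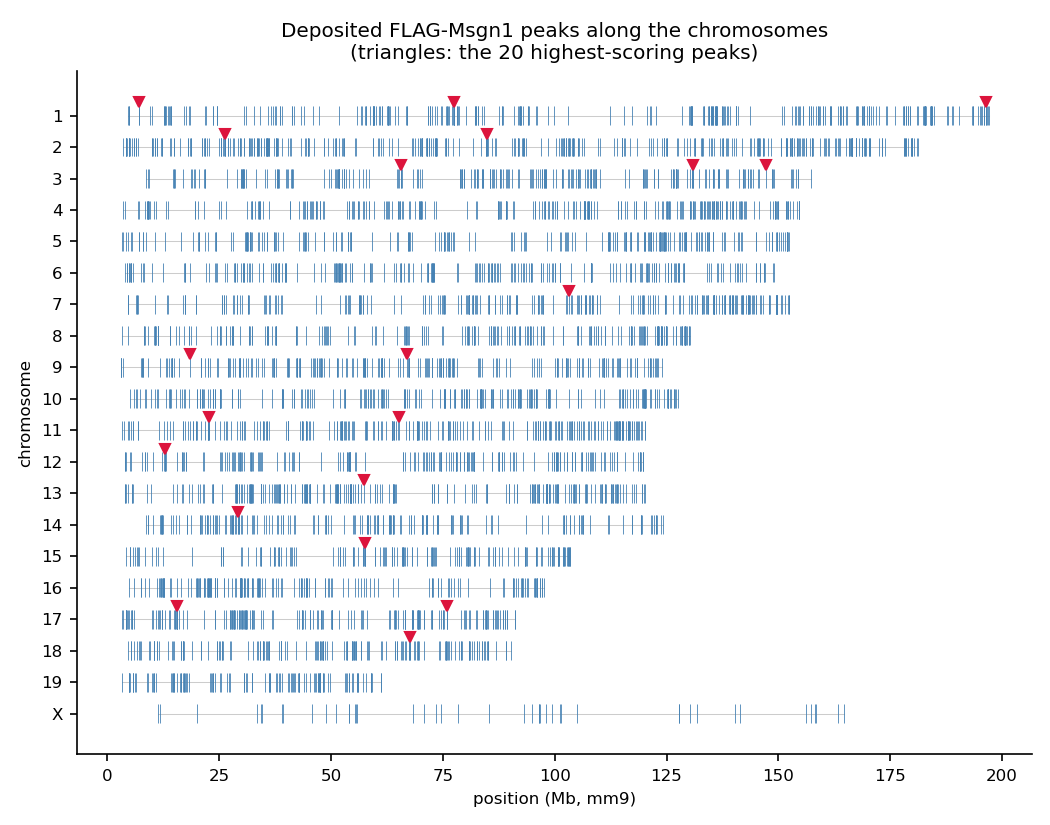
Each vertical line is 1 of the 4087 deposited peaks, placed by chromosome (vertical axis) and position in Mb on mm9 (horizontal axis), and triangles mark the 20 highest-scoring peaks. Peaks lie along all 19 autosomes, and chromosome X holds 44.

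Higher-scoring peaks were wider. With the list divided into 5 equal bins by score, the median width was 595 bp in the lowest bin (scores of 50 to 56.0), 676 bp in the middle bin and 837 bp in the highest bin (122 to 1107). Across peaks, Spearman's rho of score and width was 0.464, outside the range of −0.0565 to 0.0546 given by 1000 permutations of the scores. Peaks are not independent replicates, so this describes the list. Score and width also come from the same peak calling on the same libraries. The permutations cannot separate a link made by that calling from any other. Of the 20 highest-scoring peaks, 19 were wider than the median of the list.

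The widest peak was not among the highest-scoring ones. It lay at chr9:3024472-3027974, was 3503 bp wide and scored 181, at rank 385. It was 1 of 4 peaks within 32.9 kb at the start of the listed part of chromosome 9. The others were chr9:3003814-3006127 (2314 bp, score 80.8), chr9:3031699-3032885 (1187 bp, score 72.9) and chr9:3035547-3036759 (1213 bp, score 93.1). The median width of the 4 was 1764 bp. The 1961 other peaks with scores in or near their range had a median of 730 bp and a 95th percentile of 1004 bp. These 4 were singled out after their widths had been seen, so their widths are given as values and were not tested. Repeats and mappability were not examined there, so whether the 4 mark Msgn1 binding is unknown. The second widest peak of the list, chr2:84971004-84973477, was 2474 bp wide and scored 563, at rank 16.

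**Figure D2:**
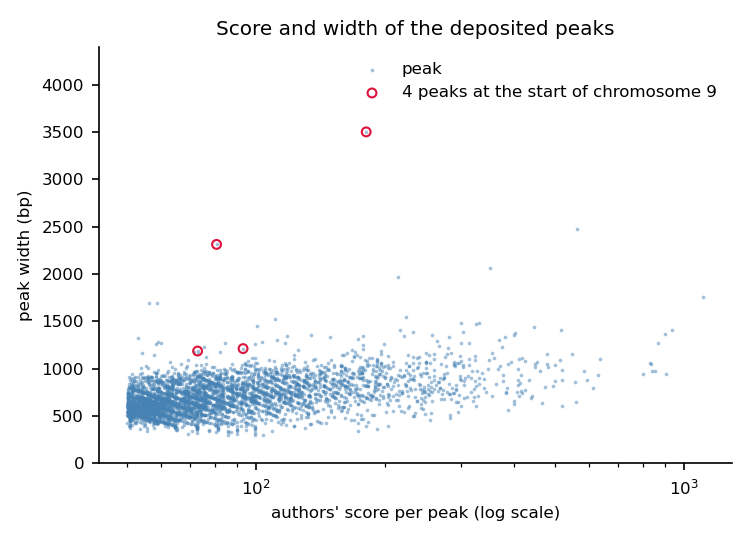
Each point is 1 deposited peak, with the authors' score on a log axis and its width in bp on the vertical axis; circles mark the 4 peaks at the start of chromosome 9. Width increases with score (Spearman's rho 0.464), and the 4 circled peaks, singled out after their widths had been seen, are 1187 to 3503 bp wide.

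Chromosome X carried far fewer peaks per Mb than any autosome. The 19 autosomes had 1.72 ± 0.203 peaks per Mb (mean ± SD over chromosomes), from 1.46 on chromosome 5 to 2.06 on chromosome 2, which alone held 367 peaks. The 95% exact Poisson intervals of chromosome 2 (1.86 to 2.29) and chromosome 11 (1.81 to 2.34) lay above that of chromosome 5 (1.27 to 1.67). So did those of chromosome 13 (1.70 to 2.21) and chromosome 17 (1.70 to 2.30). These chromosomes were picked after all densities had been seen. The intervals also treat peaks as independent, although peaks lay in runs, so a difference between autosomes beyond counting error was not tested. Chromosome X had 44 peaks, or 1.08% of the list (95% exact binomial interval 0.783 to 1.44%). That was 0.287 peaks per Mb (95% exact Poisson interval 0.209 to 0.386) and 0.167 times the autosomal mean. X was the lowest of the 20 chromosomes. An exact permutation of 1 chromosome against 19 cannot give a one-sided p below 0.05, which is the value here. The comparison was chosen after the list had been seen, so this value only restates the rank of X.

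The median score of the peaks on X was 78.9 and that of autosomal peaks 72.8. The X median lay at percentile 82.5 of 10000 random sets of 44 autosomal peaks. Scores of at least 100 were reached by 9 X peaks (20.5%) and by 28.7% of autosomal peaks. The highest X peak, chrX:34586710-34587391, scored 274 and ranked 150th. The 4 longest stretches between neighbouring peaks in the whole list were all on X, and the longest ran for 22.9 Mb, from chrX:104912351 to chrX:127846667. Random placement of the peaks within the span of their chromosomes could also give a distance above 24590000 bp. The length of these stretches is thus not a result apart from the low density of X.

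**Figure D3:**
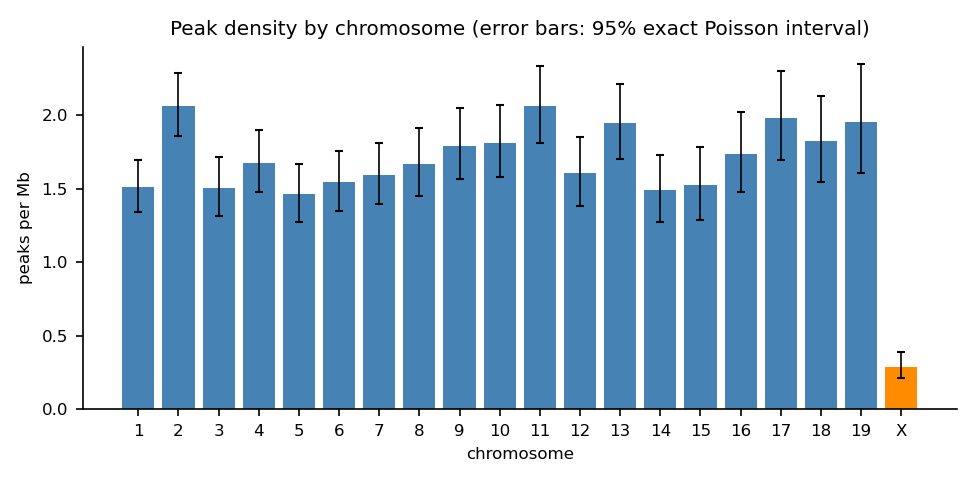
Bars give peaks per Mb for each chromosome, from the span between its first and last peak, and error bars are 95% exact Poisson intervals of the peak count. Autosomes lie between 1.46 and 2.06 peaks per Mb, and X lies at 0.287.

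Across the 19 autosomes the number of peaks followed the length of the chromosome. Pearson's r between span and peak number was 0.883 and Spearman's rho 0.853, each with a permutation p of 1.0e-05, the smallest that 100000 resamples can give, and an adjusted p of 2.0e-05. Without chromosomes 1 and 19, the farthest from the median span, r was 0.845. With the number of protein-coding genes per chromosome in GRCm38.p6, r was 0.727 (permutation p = 5.4e-04, adjusted 5.4e-04) and rho 0.788 (permutation p = 1.7e-04, adjusted 1.7e-04). Without chromosomes 7 and 2, the farthest from the median gene number, r was 0.733. These were the 2 relations computed.

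More neighbouring peaks lay at short distances than random placement gave, and more at long distances too. The placements kept the peak number and the span of each chromosome. The excess at long distances is therefore tied to that at short ones and is not a separate result. The median distance between neighbours was 278 kb, below the 380 to 428 kb of 1000 random placements. Of 4067 neighbouring pairs, 68 were at most 1 kb apart against a random mean of 11.9 (highest 30), and 257 were at most 10 kb apart against 74.4 (highest 104). At 50 kb there were 696 pairs against 340 (highest 402). At 1000 kb there were 3371 pairs against 3311, within the range of the placements (3267 to 3374) but near its upper end.

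**Figure D4:**
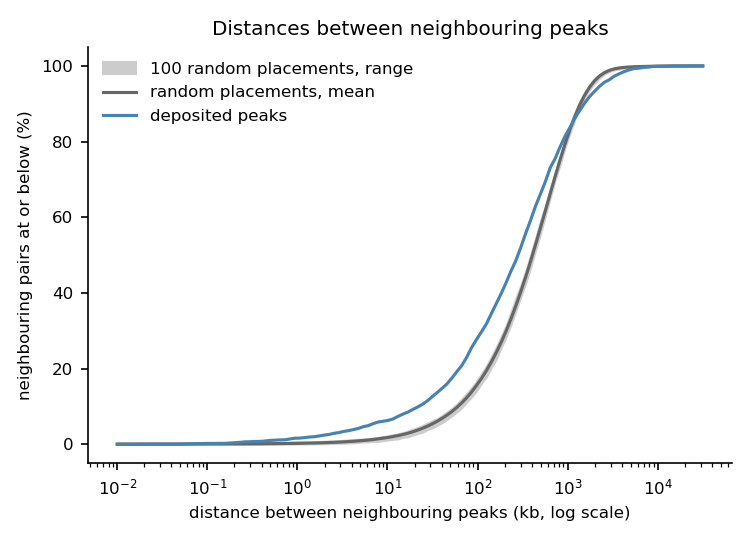
The blue line gives the percentage of neighbouring peak pairs at or below each distance in kb (log axis), the dark grey line the mean of 100 random placements and the light grey band their range. The deposited peaks lie above the band at 1, 10, 50 and 100 kb, with 17.1% of pairs at most 50 kb apart, and below it at 2254000 bp.

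There were 116 runs of 3 or more peaks, each within 50 kb of the next. They held 397 peaks, or 9.71% of the list. Random placement gave 26.5 such runs on average and 45 at most, so the observed number was 4.38 times the random mean. When each peak was placed only within its own 10 Mb stretch, the random mean was 35.8 and the highest 56. Within 2 Mb stretches the random mean was 49.6 and the highest 71, so the ratio was 2.34. The 1168 peaks scoring at least 100 formed 4 runs against a random mean of 0.707, a ratio of 5.66, and 5 of 1000 placements gave as many or more.

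The 2 longest runs by number held 7 peaks each. One spanned chr6:108170077-108260520 (90.4 kb), with scores from 63.5 to 515 and the highest peak at its end, chr6:108259113-108260520. The other spanned chr16:29758381-29852323 (93.9 kb), with scores from 55.0 to 460 and the highest peak at chr16:29800100-29801074. Another 8 runs held 5 peaks each. Among them chr1:77423373-77461819 (38.4 kb) contained the peak ranked 12th in the list, and its median score was 55.9. The others with 5 peaks and a top score above 200 were chr2:168605326-168669131, chr13:98315972-98344483, chr10:83523224-83574642 and chr2:151797741-151917855. The eighth-ranked peak of the list, chr17:15577098-15578149, belonged to a run of 3.

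**Figure D5:**
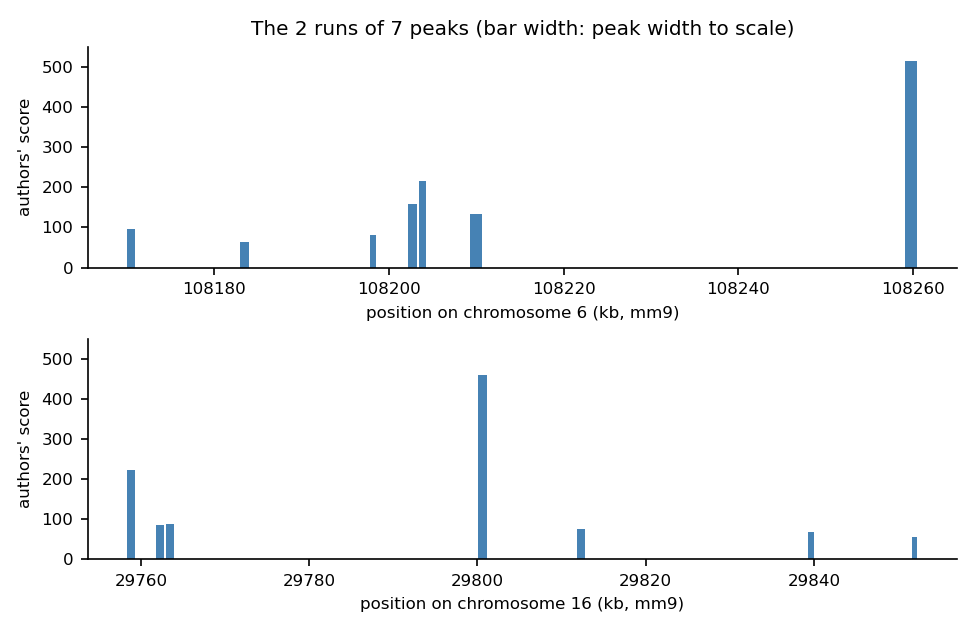
The 2 panels show the runs of 7 peaks on chromosomes 6 and 16, with position in kb on mm9 on the horizontal axis, bar width to scale with peak width, and bar height the authors' score. In each run 1 peak stands above the others, at 515 on chromosome 6 and 460 on chromosome 16.

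Peaks in runs of 3 or more had a median score of 76.2 and the 2860 peaks with no other within 50 kb had 72.6. The median of the 397 run peaks lay at percentile 97.2 of 10000 random sets of that size, just inside the central range of 69.2 to 76.4 that held 95% of them. The difference from single peaks, 3.67, depended on the gap limit: it was 8.93 with gaps of at most 20 kb and 4.90 with gaps of at most 100 kb. The run medians at these limits lay at percentiles 99.1 and 99.99, both outside the central 95%. The difference itself was not placed among random sets. No correlation between the scores of neighbours within 50 kb was detected: over 696 pairs Spearman's rho was 0.0264, within the −0.0732 to 0.0745 that held the central 95% of 1000 permutations of the scores.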

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

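All alternatives below were chosen after seeing the data, except leaving out peaks on unplaced or mitochondrial sequence, which kept 4087 peaks. The settings planned for comparisons that needed genes or sequence of mm9 were not run. A stricter limit left 1168 peaks at a score of 100 or more, so the size of the list depends on the score limit. The lists of the highest-scoring peaks held 2044 and 500 by their definition. Joining peaks less than 1 kb apart left 4019, and less than 10 kb apart 3830. The ratio of observed to random runs stayed above 1 in 13 of 13 alternatives, from 1.71 to 41.3. The observed number of runs exceeded each of the 1000 placements in 11 of them. In the other two the ratios were 5.66 (score of 100 or more) and 19.6 (top 500), on 4 and 1 runs, which 5 and 51 of the 1000 placements reached or passed. X had the lowest density of the 20 chromosomes in 7 of 7 alternatives, at 0.119 to 0.221 times the autosomal mean. The lowest ratio, 0.119, was at a score of 100 or more, where X held 9 peaks. Among the top 500 peaks, X held 6. Joining peaks left the X density at 0.287 per Mb. These alternatives reuse the same list and are not independent of each other. The correlation of score and width was 0.273 to 0.464 in 3 alternatives, above the highest permuted value in each. The median score of peaks in runs exceeded that of single peaks by 3.67 with gaps of at most 50 kb, 8.93 at 20 kb and 4.90 at 100 kb. The medians of the run peaks, not the differences, lay at percentiles 97.2, 99.1 and 99.99 of random sets. The cause was not tested. Replicates could not be left out, since each group has 1 library, and no value here separates Msgn1 binding from differences between these 2 libraries.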

Other observations

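All tests in this part were chosen after the peak list had been seen. The tests of gene number and of copy number on X were also written after their result was known, and the 3 tests of runs before any run had been counted.

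Chromosome X held 0.167 times the autosomal peak density. A lower number of genes does not account for all of it: X had 4.55 peaks per 100 protein-coding genes (GRCm38.p6), while the autosomes ranged from 11.6 on chromosome 7 to 30.5 on chromosome 18. A single copy of X in place of a pair could lower both libraries there, so that fewer places pass the limit; the labels used here do not give the karyotype. If scores on X were halved, the autosomal density at a score of 100 or more, 0.489 per Mb, would be the value to find. The X interval of 0.209 to 0.386 lies below that value. However, the lowest autosome at that score limit had 0.383 peaks per Mb, which lies inside the X interval. The halving is an assumption, so this explanation cannot be told apart from others, and no biological explanation was tested, since no group of the design bears on X. Mappability on X stays open too, as no sequence was used here.

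Runs of neighbouring peaks may in part be single bound stretches that the caller split, but joining peaks less than 10 kb apart left 59 runs of 3 or more, against a random mean of 21.9 and a highest value of 42. Broad differences in peak density between stretches of 10 Mb gave at most 56 runs in 1000 placements, against 116 observed. Weak peaks near the score limit are not the whole source, since the 2044 highest-scoring peaks formed 26 runs, against a random mean of 3.61 and a highest value of 11. Density that differs over stretches of 2 Mb gave a mean of 49.6 runs and at most 71. Each explanation was tested alone, and the joined peaks and the highest-scoring peaks were placed anywhere in the span of their chromosome. Combinations, such as split peaks together with local density, were not tested and stay open. Density at finer scale, repeats and copy number differences stay open, and no biological explanation was tested, since the design has no second condition.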
